A study of Homo sapiens with 9 samples.

How the data were processed

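The 9 RNA sequencing libraries are labelled as BT549 cells, 3 transfected with a control siRNA (siNC) and 3 each with siWFDC21P-1 or siWFDC21P-2 (5 µl of a 10 µM stock, harvest after 48 h, 1 µg of RNA per library). The deposited values are FPKM per Ensembl gene, calculated by the authors. The processing notes of the submitters name HISAT2 2.1.0, Bowtie2 2.2.3, HTSeq 0.6.0 and the genome build hg38, without saying which step used which aligner. Whether the libraries keep the strand is not stated.

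The gene tables came in 2 naming styles. Style A (siNC replicates 1 and 2, siWFDC21P-1 replicates 1 to 3) lists 34377 genes, style B (siNC replicate 3, siWFDC21P-2 replicates 1 to 3) lists 29104, and 26636 are in both. In each library 95.8 to 96.4% of the low FPKM values were multiples of 1 read (to within 0.02 reads), which allowed whole reads to be recovered for 24994 of the common genes (93.8%). The same step gave the FPKM denominator of each library: 29.2, 28.3 and 16.3 M reads for siNC replicates 1 to 3, 28.9, 29.7 and 28.1 M for siWFDC21P-1, and 17.4, 16.7 and 17.2 M for siWFDC21P-2. At that depth 1 FPKM on a 1 kb transcript corresponds to about 28.1 to 29.7 reads in style A and 16.3 to 17.4 in style B. Intervals on single values (95%) are exact Poisson or binomial intervals on the recovered reads and cover counting error only. The libraries were checked for duplicates, and none were found.

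Genes with a mean of at least 1 FPKM over the 9 libraries (13014) were tested as log2(FPKM + 1) in limma 3.58.1 (R 4.3.3), with intensity-trended empirical Bayes variances, group and naming style in the model and the Benjamini-Hochberg procedure at 0.05 over all tested genes. The contrasts were siWFDC21P-1 and siWFDC21P-2 against siNC, the difference between these 2, the genes passing in both with the same sign, and the naming style. With the naming style in the model, siWFDC21P-2 is compared with siNC replicate 3 alone, and the spread is taken from all 9 libraries. The p-values measure the spread between libraries. How many independent transfections the libraries stand for is not stated in the labels. The names of the siWFDC21P-2 libraries end in different numbers after "si", and the labels do not say what these numbers mark. All were taken as replicates of siWFDC21P-2, as their titles give. WFDC21P was also compared by an exact permutation test.

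The 3 expression sets were defined after the values had been seen, by average-linkage clustering on 1 minus the Pearson r, split at a height of 0.15. All fits with the sets in place of the naming style, the pooling of both siRNAs, the count of genes on one side of the control in all 6 knockdown libraries, the fits without the libraries of set 2, and limma-voom on the recovered reads were likewise added after the values had been seen.

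Gene lists (37, with 907 genes, 757 of them tested) were fixed before the values arrived, and the 35 with at least 5 tested members were tested with limma camera at a preset correlation of 0.01, with the correlation estimated from the data, and with limma fry. The lists of leukocyte and endothelial markers had too few tested members. Adjustment over the list alone means the Benjamini-Hochberg procedure over its members.

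Genes to be named were chosen by a rule fixed beforehand. For each siRNA it took WFDC21P, then the 10 genes with the largest positive and the 10 with the largest negative fold change among those with a symbol, an adjusted p of at most 0.05 and every knockdown library on the same side of every control of its naming style. Where none passed, it took the 5 higher and 5 lower genes with the smallest unadjusted p. For both siRNAs the rule was the same on the genes passing in both, and for each list up to 4 members with the smallest adjusted p, of which at most 2 are given. The marker genes, the genes passing with the sets in the model or after leaving out a library, and the genes on one side in all 6 libraries were chosen after their values had been seen.

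The model was tested on simulated data with the set means and the residual spread (sets in the model) of the real values, with 50 of 13014 genes changed at each step. With the naming style in the model, a log2 change of 1 was called in 2% of the changed genes for siWFDC21P-1 and in 0% for siWFDC21P-2, a change of 2 in 42% and 22%, and a change of 4 in 88% and 66%. With the sets and both siRNAs pooled, a change of 1 was called in 74% and a change of 2 in 96%. The changed genes were drawn only from those with a mean log2(FPKM + 1) above 2. Each change was put in equal size into every knockdown library, with independent normal noise. The shares therefore hold for a uniform response of the better expressed genes. They do not cover libraries that respond unequally, such as siWFDC21P-2 replicate 1, which lay next to its control.

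Each result was recomputed without the naming style, within the style of the knockdown alone, with the replicate number as a block, with pseudocounts of 0.1 and 0.5, with no filter or a mean of at least 5 FPKM, after median-of-ratios, quantile or TPM scaling, with untrended or robust variances, with a fold-change minimum, and leaving out each library in turn. Results were also recomputed for other splits of the libraries. Gene coordinates are from GENCODE 29 (hg38). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.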

Results

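RNA sequencing was carried out on cells labelled BT549, a human triple-negative breast cancer line with a mesenchymal-like phenotype, after transfection with a control siRNA (siNC) or with 1 of 2 siRNAs against the pseudogene transcript WFDC21P (siWFDC21P-1 and siWFDC21P-2). Each of the 3 groups held 3 libraries, harvested 48 h after transfection. The values were FPKM (fragments per kilobase of transcript, scaled to the mapped reads) per Ensembl gene. The libraries carried 2 naming styles, and their gene tables differed accordingly. Style A held siNC replicates 1 and 2 and the 3 siWFDC21P-1 libraries, and style B held siNC replicate 3 and the 3 siWFDC21P-2 libraries. Whole reads recovered from the low FPKM values put the depth at 28.1 to 29.7 M reads per library in style A and at 16.3 to 17.4 M in style B. Of 26636 genes listed in both, 13014 with a mean of at least 1 FPKM over the 9 libraries were tested.

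WFDC21P (ENSG00000261040; hg38, chromosome 17, 60083566 to 60091885, minus strand; annotated as a transcribed unitary pseudogene) was the target, and its level was examined first. It stood at 3.08 FPKM in siNC replicate 1, at 0.129 in the library labelled siNC replicate 2 and at 6.87 in siNC replicate 3. The siWFDC21P-1 libraries had 0.0629, 0.767 and 0.227 FPKM, and the siWFDC21P-2 libraries had 4.13, 3.32 and 2.12 FPKM. The group means were 3.36 ± 3.38 FPKM for siNC, 0.352 ± 0.368 for siWFDC21P-1 and 3.19 ± 1.01 for siWFDC21P-2 (SD, n = 3 each). The exact two-sided permutation test gave p = 0.3 for siWFDC21P-1 and p = 1 for siWFDC21P-2 against siNC, where 0.1 is the smallest p that 3 against 3 libraries can give. In the limma fit with the naming style as a term, the log2 fold change on the log2(FPKM + 1) scale was -0.70 ± 0.54 (SE) for siWFDC21P-1 and -0.94 ± 0.69 for siWFDC21P-2, and neither passed (adjusted p = 1.0 for both). The first value became 0.23 without siNC replicate 1, and the second became 0.31 without the naming-style term.

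The libraries fell into 3 expression sets that did not follow the siRNA groups, and WFDC21P was therefore also compared with the siNC library of the same set. Set 1 held siNC replicate 1 and siWFDC21P-1 replicates 1 and 2, set 2 held the library labelled siNC replicate 2 and siWFDC21P-1 replicate 3, and set 3 held the 4 libraries of style B. In set 1, WFDC21P was at 2.04% of its control in siWFDC21P-1 replicate 1 (2 reads against 99; 95% counting interval 0.244 to 7.58%) and at 24.9% in replicate 2 (15.4 to 38.9%). In set 2 both libraries were near the floor, with 7 reads in siWFDC21P-1 replicate 3 and 4 in the control, so that no difference was detectable at this depth (176%, 44.8 to 821%). In set 3, WFDC21P was at 60.2% (44.8 to 80.5%), 48.3% (34.9 to 66.2%) and 30.8% (21.03 to 44.4%) of its control in siWFDC21P-2 replicates 1, 2 and 3. The intervals cover counting error only. WFDC21P overlaps the lincRNA AC025048.4 on the plus strand (60079309 to 60088695), and reads from the 2 genes cannot be told apart where the library does not keep the strand.

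**Figure D1:**
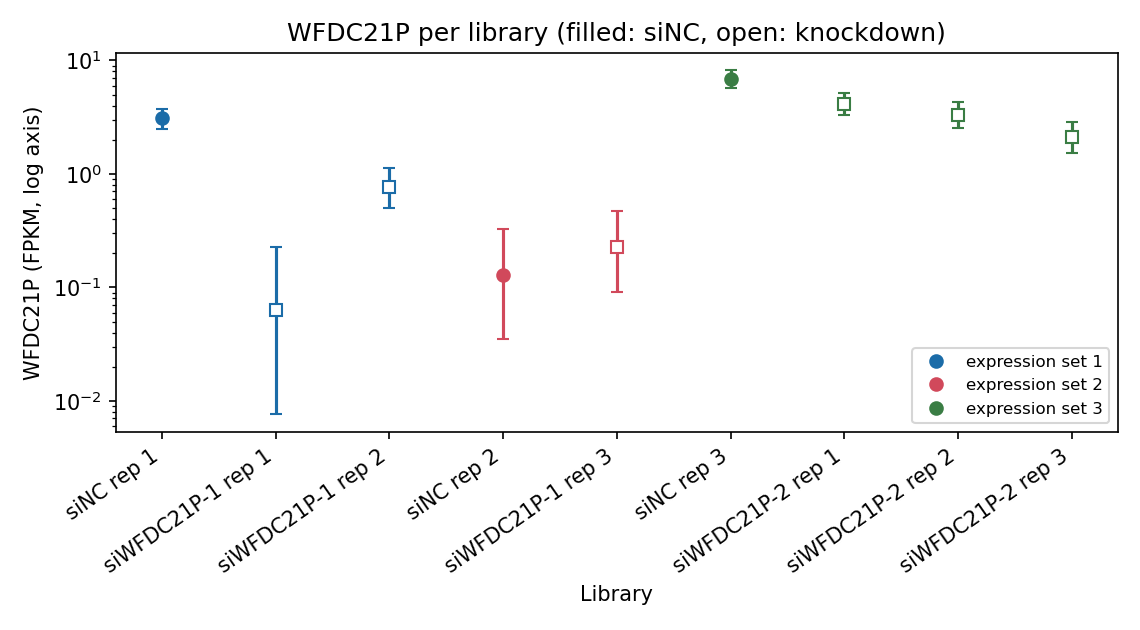
WFDC21P in FPKM (log axis) in each of the 9 libraries, ordered by expression set, with filled circles for siNC, open squares for the knockdown libraries and bars for the 95% counting interval. In sets 1 and 3 each knockdown library lies below its control, and in set 2 the control (0.129 FPKM) and the knockdown library (0.227 FPKM) overlap.

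Many epithelial and mesenchymal markers differed between the sets far more than between control and knockdown. VIM (vimentin, a mesenchymal intermediate filament) was at 162 to 310 FPKM in set 3, at 38.5 to 41.0 in set 1 and at 0.517 to 0.699 in set 2. The epithelial adhesion genes EPCAM and CDH1 (E-cadherin) reached 209 and 42.7 FPKM in the library labelled siNC replicate 2 and 228 and 59.6 in siWFDC21P-1 replicate 3, and stayed at or below 0.0731 and 1.16 in the other 7 libraries. The simple-epithelial keratin gene KRT19 was at 925 and 474 FPKM in set 2 and at or below 0.872 elsewhere, whereas KRT8 was abundant in sets 1 and 2 (93.4 to 293 FPKM) and low in set 3 (3.99 to 5.44). CDH2 (N-cadherin), the fibroblast marker THY1, the collagen gene COL1A2 and the matrix protease gene MMP14 were abundant in set 3 (at least 14.7, 43.6, 56.2 and 71.9 FPKM) and at or below 0.238 in sets 1 and 2. Across the tested genes, the Pearson correlation of log2(FPKM + 1) was 0.927 to 0.986 within sets and 0.658 to 0.744 between them. Sets 1 and 2 shared style A, and still correlated at 0.711 to 0.744.

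**Figure D2:**
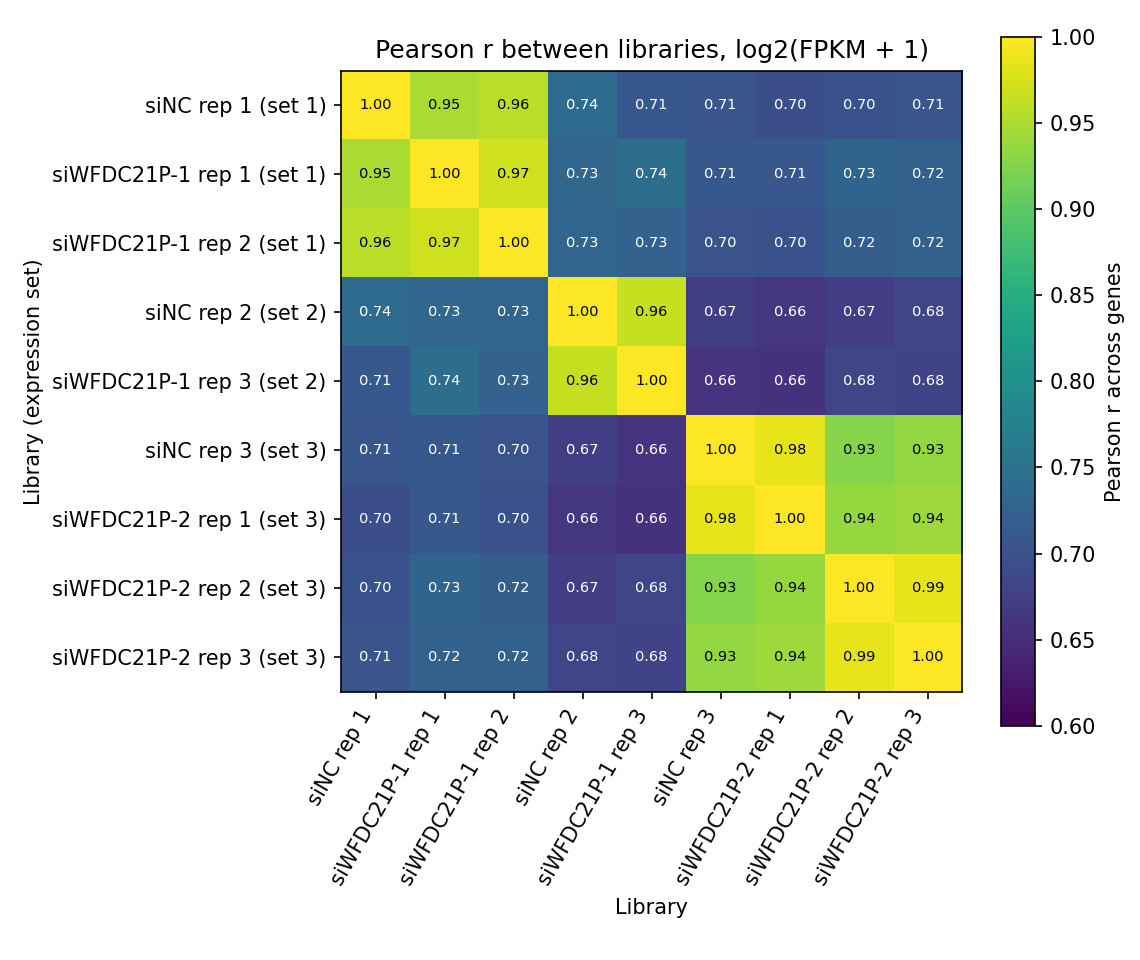
Pearson r across 13014 genes between each pair of the 9 libraries, on log2(FPKM + 1), ordered by expression set. 3 groups of libraries stand out, with r of 0.927 or more inside and of at most 0.744 outside, and each holds 1 siNC library.

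**Figure D3:**
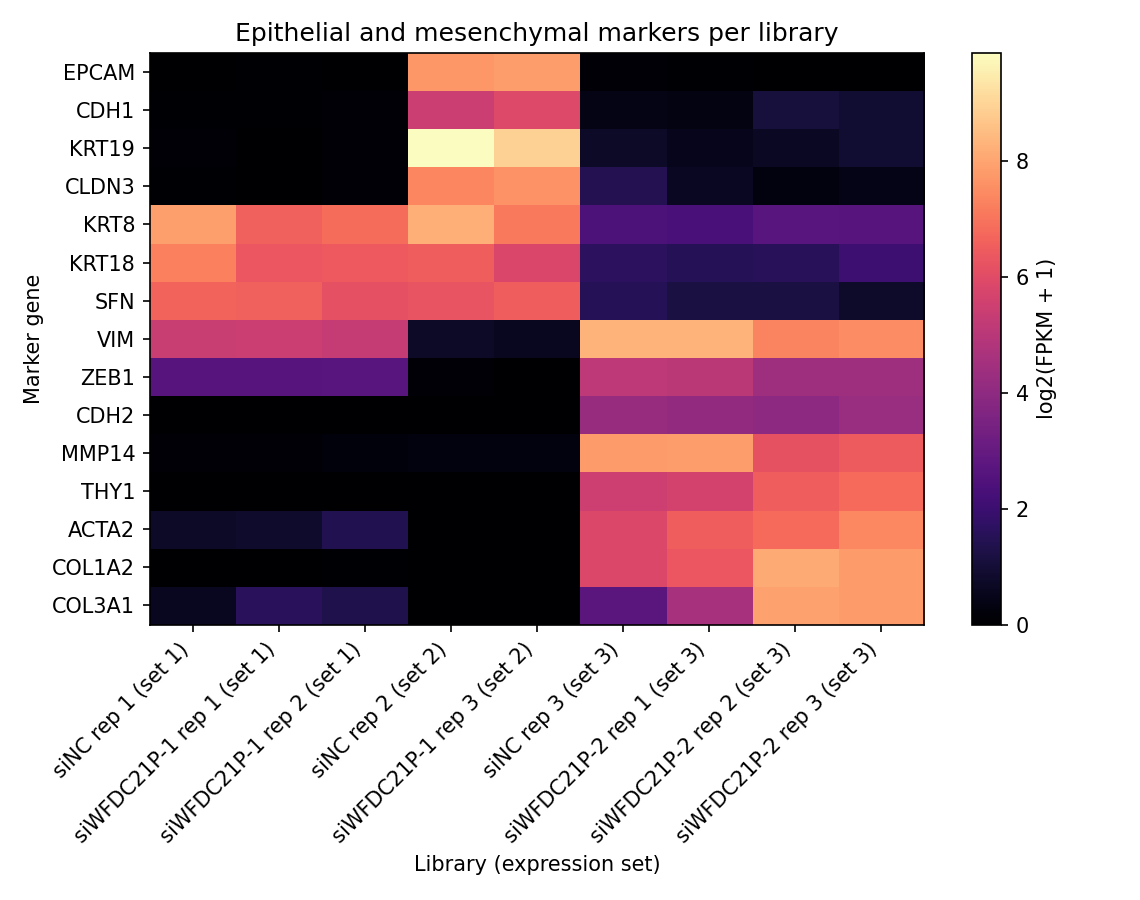
Levels of 15 epithelial and mesenchymal marker genes in each library, as log2(FPKM + 1). EPCAM, CDH1, KRT19 and CLDN3 are high in the 2 libraries of set 2, and CDH2, MMP14, THY1 and COL1A2 are high in the 4 libraries of set 3.

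The first comparison asked which genes change with siWFDC21P-1. No gene passed (limma, Benjamini-Hochberg adjusted p of at most 0.05), 708 of 13014 had an unadjusted p under 0.05 (489 higher, 219 lower), and limma-voom on the recovered reads also called 0. The 5 genes with the smallest p on the higher side were GTF3A, a transcription factor for 5S rRNA, GANAB, the catalytic subunit of glucosidase II in the endoplasmic reticulum, ERLIN2, TCF3, an E-protein transcription factor, and MIR4645. GTF3A had 13.1 and 17.2 FPKM in siNC replicates 1 and 2 and 48.7, 41.8 and 41.7 in the knockdown libraries (log2 fold change 1.49 ± 0.20, SE), and GANAB had 24.9 and 37.8 against 92.6, 91.1 and 116 (1.66 ± 0.23). The fold changes were 1.26 ± 0.19 for ERLIN2, 1.32 ± 0.21 for TCF3 and 2.30 ± 0.38 for MIR4645. On the lower side were RNU6-611P (-1.24 ± 0.21), VCL (-2.26 ± 0.44), KRT8 (-1.21 ± 0.24), NCEH1 (-1.12 ± 0.23) and ANKRD61 (-1.19 ± 0.24). VCL, the focal adhesion protein vinculin, had 48.3 and 47.4 FPKM in the controls and 6.95, 11.1 and 9.97 in the knockdown libraries, and 53.05 against 49.3, 19.9 and 56.0 in siNC replicate 3 and the siWFDC21P-2 libraries.

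With the expression sets in place of the naming style as a term, a fit chosen after the values had been seen, 3 genes passed for siWFDC21P-1. GANAB (chromosome 11, 62624826 to 62646726, minus strand; 1.74 ± 0.16) and RPL26L1, a ribosomal protein L26 paralog (chromosome 5, 172958729 to 172969771, plus strand; 1.59 ± 0.15), rose, and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36676460 to 36687339, plus strand; -2.42 ± 0.21), fell, each at a limma adjusted p of 0.0442. CDKN1A was at 324 FPKM in siNC replicate 1 and at 65.8 and 54.6 in the knockdown libraries of set 1, and at 50.6 and 8.55 in control and knockdown of set 2. At an unadjusted p under 0.05 there were 1790 genes. The count of 3 became 0 without siNC replicate 1, without siWFDC21P-1 replicate 1 and without siWFDC21P-2 replicate 2 or 3, and 153 (121 higher, 32 lower) without siWFDC21P-2 replicate 1.

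Of 35 gene lists fixed before the data were examined, 6 passed for siWFDC21P-1 (limma camera with a preset correlation of 0.01, Benjamini-Hochberg over the lists). Core histones rose (median log2 fold change 0.78 over 11 genes, adjusted p = 0.00812; adjusted p = 0.769 with an estimated correlation), with 9 of 11 higher than the control of their set in all 3 knockdown libraries. Their leading members were H2BC5, at 4.44 and 5.15 FPKM in the controls and 14.4, 33.8 and 22.4 in the knockdown libraries, and H2BC8. MYC targets and ribosome biogenesis rose (0.33, adjusted p = 0.0139; adjusted p = 0.769 with an estimated correlation; 7 of 26 higher in all 3). Its leading members were CAD, an enzyme of pyrimidine synthesis (20.6 and 17.6 against 41.3, 41.2 and 29.8 FPKM), and DKC1. G2/M and mitosis genes rose (0.28, adjusted p = 0.0453; adjusted p = 0.871 with an estimated correlation; 26 of 37 higher in all 3), among them CENPF (0.96 ± 0.43) and AURKB (0.89 ± 0.42). The type I interferon response (-0.36; 13 of 27 lower in all 3), the hypoxia response (-0.32; 11 of 23) and integrins and focal adhesion (-0.18; 10 of 28 lower and 3 higher in all 3) fell, each at an adjusted p of 0.0453. For these 3 lists, adjusted p = 0.769 with an estimated correlation. Some leading members went against their list. ERO1A, an oxidoreductase of the endoplasmic reticulum, had a fold change of 1.12 ± 0.30 among the hypoxia genes, where ANGPTL4 had -1.57 ± 0.49. The interferon-induced membrane protein BST2 had 0.83 ± 0.36 beside OAS3, an oligoadenylate synthetase (-1.43 ± 0.44). None of these members passed on its own, and without siNC replicate 1 the fold changes were 0.40 for CENPF, 0.45 for AURKB, 0.15 for DKC1 and -0.76 for OAS3. Without siNC replicate 2 they were 0.51 for BST2 and 0.43 for H2BC8.

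None of the 6 lists thus held with an estimated correlation (adjusted p = 0.769 or more), and 0 of 35 lists passed limma fry. Adjusted over the list alone 1 integrin gene, VCL, and 0 members of the other 5 lists passed. With the expression sets as a term all 6 kept their direction and passed, together with 6 more. Glycolysis (-0.19), matrix proteases and inhibitors (-0.16), immediate early genes and AP-1 (-0.15), oxidative stress and NRF2 targets (-0.26) and the epithelial to mesenchymal transition (-0.03) were lower, and cholesterol biosynthesis (0.24) was higher (adjusted p = 0.649 or more with an estimated correlation for all 12). With limma fry, matrix proteases and inhibitors alone passed among these 12, and 7 lists passed its mixed test, which ignores direction. The count of 6 became 3 without siNC replicate 1 or siWFDC21P-1 replicate 3, and 10 without siNC replicate 2 or siWFDC21P-1 replicate 1.

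The second comparison asked the same of siWFDC21P-2, whose 3 libraries had a single control of their own naming style, siNC replicate 3. No gene passed (limma), 190 had an unadjusted p under 0.05 (114 higher, 76 lower), and limma-voom called 0. The smallest p on the higher side belonged to MT1E, a metallothionein (21.2 FPKM in the control; 44.5, 45.8 and 42.3 in the knockdown libraries; 1.03 ± 0.21), MIR6753 (1.75 ± 0.40), THOC7 (1.06 ± 0.25), GANAB (82.0 FPKM against 192, 201 and 182; 1.22 ± 0.30) and MIR1244-3 (2.21 ± 0.55). On the lower side were UGCG, the ceramide glucosyltransferase (113 FPKM against 43.4, 30.7 and 21.7; -1.85 ± 0.37), SNORA75 (-1.46 ± 0.35), the interferon-induced genes IFI6 (213 FPKM against 95.2, 40.6 and 32.5; -2.06 ± 0.53) and IFI44L (-1.86 ± 0.54), and the pseudogene GLRX5P2 (-1.57 ± 0.45), which can share reads with its parent gene. MIR4645, MIR6753, MIR1244-3 and SNORA75 are short RNAs, for which FPKM from standard libraries is uncertain. The set term left the siWFDC21P-2 fold changes as they were and also gave 0 genes, with 682 at an unadjusted p under 0.05. Without siWFDC21P-2 replicate 1, 3 genes passed with the naming-style term, all lower: KLHDC7B and the inducible heat shock genes HSPA6 and HSPA1B.

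For siWFDC21P-2, 14 lists passed, 8 lower and 6 higher, and none of them held with an estimated correlation (adjusted p = 0.32 or more). The unfolded protein and integrated stress response fell (median -1.35, adjusted p = 7.69e-16; adjusted p = 0.32 with an estimated correlation), with 22 of 29 members lower in all 3 libraries. PSAT1, an enzyme of serine synthesis, was at 209 FPKM in the control and 105, 76.2 and 92.1 in the knockdown libraries and VLDLR at 6.78 against 3.75, 0.653 and 0.897. The type I interferon response fell (-0.93, adjusted p = 1.34e-13; adjusted p = 0.32 with an estimated correlation), with 27 of 27 members lower in all 3 libraries. Cytosolic ribosomal proteins (-0.33, adjusted p = 1.88e-09; 17 of 50 lower in all 3; RPL13 -0.56 ± 0.36, RPL12 -0.76 ± 0.49), immediate early genes and AP-1 (-0.45, 1.19e-05; DUSP5 -1.22 ± 0.44, EGR1 -0.94 ± 0.34) and heat shock genes (-0.43, 1.39e-05; 10 of 15) fell as well. For these 3, adjusted p = 0.407, 0.32 and 0.32 with an estimated correlation. HSPA1A was at 495 FPKM in the control, at 240 in replicate 1 and at 22.5 and 25.5 in replicates 2 and 3, and HSPA1B at 484 against 231, 16.8 and 15.6. These near-identical paralogs can share reads. NF-kB and inflammatory cytokines fell (-0.59, adjusted p = 0.000244; adjusted p = 0.32 with an estimated correlation; 15 of 20). IL6 was at 14.9 FPKM against 7.59, 1.94 and 1.86 and CXCL8 at 1372 against 502, 36.2 and 97.4. Oxidative stress and NRF2 targets (-0.15, adjusted p = 0.00609; HMOX1, heme oxygenase 1, 1572 FPKM against 1048, 151 and 86.8; GCLC -0.66 ± 0.26) and apoptosis regulators (-0.10, adjusted p = 0.0244; the anti-apoptotic MCL1 -0.90 ± 0.32, the death receptor gene TNFRSF10A -1.25 ± 0.58) completed the lower lists, with adjusted p = 0.325 and 0.32 with an estimated correlation.

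On the higher side with siWFDC21P-2 were core histones (1.44, adjusted p = 2.58e-07; 10 of 11 higher in all 3; H2AC6 2.40 ± 0.85, H2AC8 1.44 ± 0.60), G2/M and mitosis (0.60, adjusted p = 2.58e-07; 22 of 37; BUB1 0.94 ± 0.37, ASPM 0.85 ± 0.47), fibroblast markers (1.01, adjusted p = 0.000204; 9 of 10) and collagens and extracellular matrix (0.84, adjusted p = 0.00609; 15 of 24). For these 4, adjusted p = 0.32, 0.5, 0.325 and 0.325 with an estimated correlation. COL3A1 was at 5.75 FPKM in the control and 22.98, 242 and 221 in the knockdown libraries, and COL1A2 at 56.2 against 80.2, 272 and 224. Oxidative phosphorylation rose (0.27, adjusted p = 0.00142; adjusted p = 0.363 with an estimated correlation; ATP5PB 0.59 ± 0.28, SDHB 0.46 ± 0.27). TGF-beta and SMAD3 targets rose (0.54, adjusted p = 0.0483; adjusted p = 0.568 with an estimated correlation; 15 of 26 higher in all 3). TGIF1, a SMAD corepressor, went against the latter list (-0.63 ± 0.34). Adjusted over the list alone, 0 members of any of the 14 lists passed, and 0 of 35 lists passed limma fry. With the set term 12 passed, and the NRF2 and apoptosis lists did not. With 1 control, chance alone puts 25% of genes below it in all 3 libraries and 25% above. Replicate 1 lay next to the control (r = 0.985), with 161 genes over 1 log2 unit apart against 1229 and 1105 for replicates 2 and 3, and its list medians were the nearest to 0 of the 3 libraries for all 9 lists plotted below.

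The third comparison asked which changes the siRNAs share. No gene passed for both with the same sign, with limma or limma-voom, and 42 genes had an unadjusted p under 0.05 for both in one direction. With the smallest larger p were GANAB, TOMM22 (a mitochondrial import receptor), C9orf78, TCF3 and KLHDC3 on the higher side, and OAS3, N4BP3, MCL1, DUSP5 (an ERK phosphatase) and SLC1A4 on the lower. TOMM22 had 14.3, 16.2 and 18.6 FPKM in the siNC libraries, 57.9, 43.0 and 35.4 with siWFDC21P-1 and 37.1, 53.1 and 50.2 with siWFDC21P-2, and MCL1 had 190, 124 and 130, then 76.6, 83.0 and 68.2, then 82.5, 63.0 and 62.7. Across genes, which are not independent replicates, the fold changes of the 2 siRNAs had r = 0.226 (Spearman 0.223), with 57.4% of the same sign; with the naming-style term the 2 contrasts used different control libraries. The correlation did not hold without the naming-style term, where all 3 controls are shared (r = -0.381; 0.499 simulated with no effect).

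Against the control of their own set, a comparison chosen after the values had been seen, 2439 genes (18.7%; 1408 higher, 1031 lower) lay on the same side in all 6 knockdown libraries. Random order within the sets would give 8.33% (1084.5 genes). Among the 6, siWFDC21P-1 replicate 3 had no detectable fall of WFDC21P (7 reads against 4 in its control). A change shared with that library, here or in the pooled fit, cannot be tied to a loss of WFDC21P. Fold changes against the own control correlated at r = 0.440 between sets 1 and 2. The values were 0.237 between sets 1 and 3 and 0.188 between sets 2 and 3. The widest margins on the higher side belonged to GANAB, TOMM22, BICD2, H2AC6, FAM210B, TCF3, PEG10, TPM4 (a tropomyosin), PRDX4 (a peroxiredoxin of the endoplasmic reticulum) and TM4SF1. The lower side held KLHDC7B, OAS3, CDKN1A, IER5, ISG15, DUSP5, MCL1, GCH1 (the first enzyme of tetrahydrobiopterin synthesis), RHEBL1 and UHMK1. CDKN1A had 11.7, 7.52 and 10.1 FPKM with siWFDC21P-2 against 23.8 in its control, and ISG15, a ubiquitin-like interferon-induced protein, had 54.2 and 86.0 against 187 in set 1, 7.48 against 13.8 in set 2 and 85.3, 38.4 and 32.4 against 210 in set 3. Pooled over both siRNAs with the sets as a term, GANAB alone passed (1.53 ± 0.14, limma adjusted p = 0.0441), 1871 genes had an unadjusted p under 0.05, and CDKN1A (-1.95 ± 0.25), OAS3 (-1.63 ± 0.22) and TPM4 (1.58 ± 0.23) had an adjusted p of 0.0969. WFDC21P itself had -0.88 ± 0.31 (adjusted p = 0.269). GANAB lost its call when any one library other than siNC replicate 3 or siWFDC21P-2 replicate 1 was left out, and 204 genes (164 higher, 40 lower) passed without siWFDC21P-2 replicate 1.

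In the pooled fit, 10 lists passed, and none held with an estimated correlation (adjusted p = 0.523 or more). The interferon response fell most clearly (median -0.61, adjusted p = 3.34e-12; 13 of 27 lower in all 6 libraries, 8 members adjusted over the list alone; adjusted p = 0.523 with an estimated correlation). G2/M and mitosis genes rose (0.52, 1.27e-08; adjusted p = 0.618 with an estimated correlation; 17 of 37 higher in all 6, with CENPA, the centromeric histone H3 variant, at 1.38 ± 0.32 and HMMR at 0.69 ± 0.19). Core histones rose (0.92, adjusted p = 8.48e-05; 9 of 11 higher in all 6, 6 adjusted over the list alone; adjusted p = 0.617 with an estimated correlation). Collagens and extracellular matrix rose (0.35, 0.0457; adjusted p = 0.646 with an estimated correlation; THBS1 1.32 ± 0.32 but FBLN1 -0.56 ± 0.15). Ribosomal proteins (-0.20, 1.14e-05; RPL7A -0.40 ± 0.20, RPL35 -0.30 ± 0.17), immediate early genes and AP-1 (-0.38, 6.27e-05; DUSP5 -1.31 ± 0.25, SPRY4 -0.96 ± 0.17; 3 adjusted over the list alone) and NF-kB and inflammatory cytokines (-0.40, 0.000898; NFKBIA -0.55 ± 0.14, TNFAIP2 -0.81 ± 0.22; 2 adjusted over the list alone) fell (adjusted p = 0.731, 0.523 and 0.523 with an estimated correlation). The unfolded protein and integrated stress response (-0.52, 0.00231; EDEM1 -0.86 ± 0.24), the hypoxia response (-0.27, 0.0103; INSIG2 -0.54 ± 0.14, but ERO1A 0.71 ± 0.22) and oxidative stress and NRF2 targets (-0.33, 0.011; NFE2L2 -0.40 ± 0.14) fell (adjusted p = 0.731, 0.523 and 0.523 with an estimated correlation). The unfolded protein list lay above its control in every siWFDC21P-1 library (median 0.05 to 0.28) and below it with siWFDC21P-2 (-2.22 to -0.24). The pooled fall is thus not shared by the libraries of both siRNAs, which also lie in different sets. The ribosomal protein list lay above its control in 3 of the 6 libraries (siWFDC21P-1 replicates 1 and 2 and siWFDC21P-2 replicate 1, medians 0.11, 0.01 and 0.02), and the collagen list was at 0.02 to 0.06 with siWFDC21P-1 against 0.21 to 1.08 with siWFDC21P-2. With limma fry 0 of the 35 lists passed in the pooled fit, and 5 passed its mixed test. Without siNC replicate 1 the value of HMMR was 0.43, and without siNC replicate 2 that of RPL35 was -0.17. Of the 24 possible choices of 1 library per set as control, 13 gave at least 10 lists. The median of the list over the 6 libraries was as extreme in 1 of the 24 choices, the siNC libraries themselves, for the interferon (-0.67), G2/M (0.54), hypoxia, immediate early, NF-kB and collagen lists. It was as extreme in 2 choices for core histones, 4 for NRF2 targets, 8 for ribosomal proteins and 9 for the unfolded protein list. The Notch and RNA interference lists, which did not pass, also had 1 of 24.

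**Figure D4:**
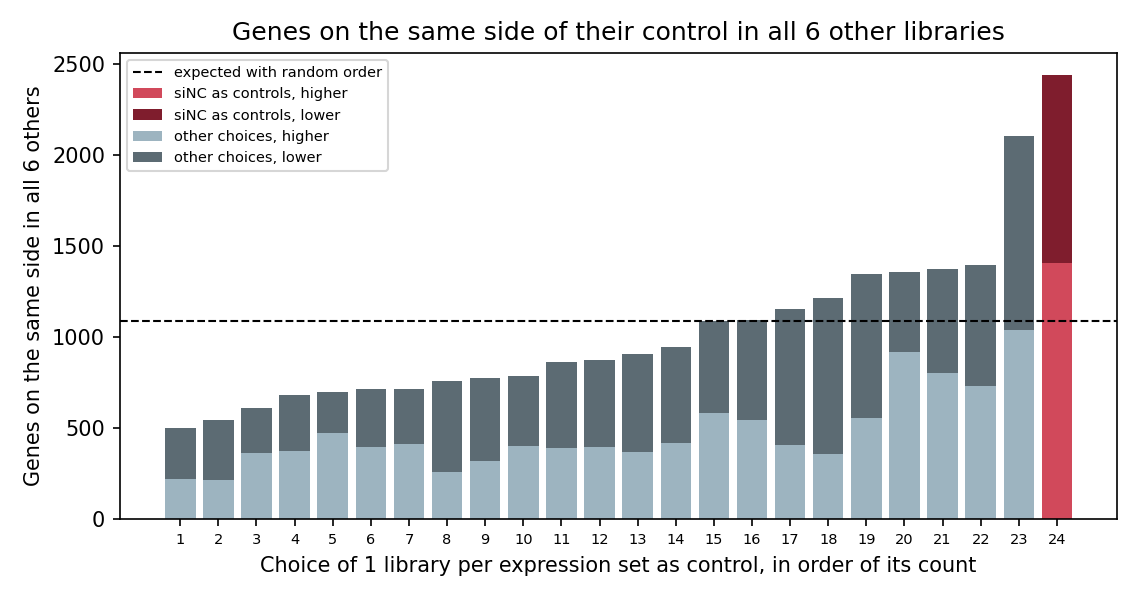
Genes on the same side of their own-set control in all 6 other libraries, for each of the 24 choices of 1 library per set as control, with higher and lower genes stacked. The siNC choice (red) gives 2439 genes, the highest of the others 2102, and the dashed line marks the 1084.5 genes of random order.

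**Figure D5:**
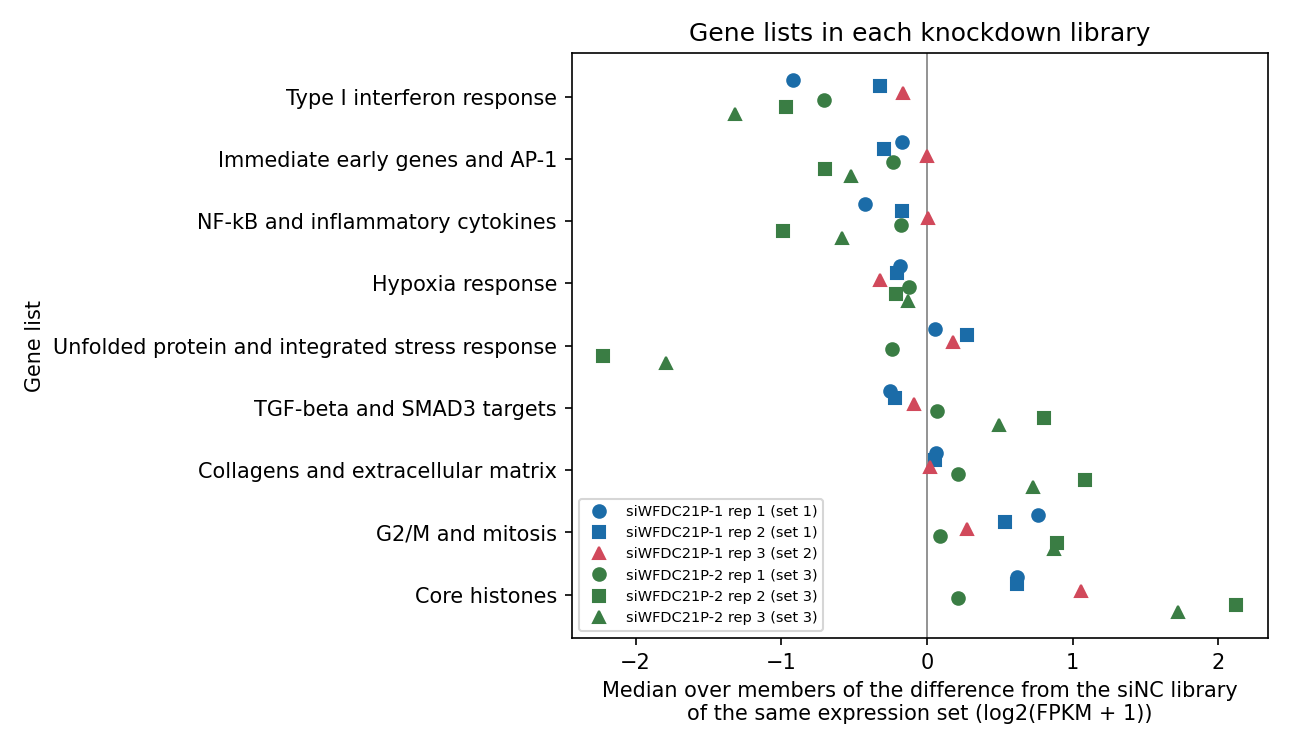
Median over the members of 9 gene lists of the difference between each knockdown library and the siNC library of its expression set, in log2(FPKM + 1), with colours for the sets. The interferon list lies below 0 in all 6 libraries (-0.17 to -1.32) and core histones and G2/M genes above 0, while the unfolded protein list lies above 0 with siWFDC21P-1 and below 0 with siWFDC21P-2.

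The fourth comparison asked whether the siRNAs differ in their effect. The siWFDC21P-1 libraries lie in sets 1 and 2 and the siWFDC21P-2 libraries in set 3 alone. A difference between the siRNAs therefore cannot be told apart from one between the sets, their gene tables or their depth. No gene passed the test of the difference (limma; 162 at an unadjusted p under 0.05; limma-voom 0). Without siWFDC21P-2 replicate 1 the heat shock gene HSPA6 passed, lower with siWFDC21P-2 (-6.92 ± 0.34, adjusted p = 0.0135). The naming styles themselves differed in 863 genes (481 higher in style B, 382 lower; limma-voom 505), and since style B is set 3, this contrast is also one between expression sets. It became 343 without siNC replicate 1 and 1071 without siWFDC21P-2 replicate 1.

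Neither siRNA gave a call for 18 lists, at adjusted p values of 0.0802 to 0.913 for siWFDC21P-1 and 0.0572 to 0.963 for siWFDC21P-2. Median fold changes for siWFDC21P-1 and then siWFDC21P-2 were -0.08 and 0.47 for the epithelial to mesenchymal transition, -0.72 and -0.05 for luminal and -0.45 and -0.00 for basal epithelial markers, -0.13 and 0.14 for glycolysis, 0.02 and 0.32 for mitochondrially encoded genes, and -0.13 and 0.27 for fatty acid synthesis. They were 0.22 and 0.06 for cholesterol biosynthesis, -0.24 and 0.03 for matrix proteases and inhibitors, 0.02 and 0.04 for DNA replication and G1/S, 0.14 and -0.04 for p53 targets, -0.02 and 0.03 for autophagy and lysosome, and -0.11 and -0.10 for MHC and antigen presentation. For the RNA interference machinery they were -0.13 and -0.08, for the Notch pathway -0.08 and -0.13, for JAK-STAT3 targets -0.08 and -0.12, for Wnt and beta-catenin targets -0.06 and 0.25, for YAP and TEAD targets 0.04 and -0.06, and for genes of 17q23 around WFDC21P -0.02 and 0.11. The controls and knockdown libraries of siWFDC21P-1 hold sets 1 and 2 in different shares, and with the sets as a term its medians were 0.06 for luminal and -0.23 for basal markers. Median and test differed in sign for apoptosis regulators, DNA replication and mitochondrially encoded genes with siWFDC21P-1, and for DNA replication and YAP and TEAD targets with siWFDC21P-2. The mean had the sign of the test in the first 3 of these and for YAP and TEAD targets, that of the median in DNA replication with siWFDC21P-2, and differed from both for 17q23 with siWFDC21P-1. It was negative for autophagy with siWFDC21P-2, where median and test were positive.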

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

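The other splits of the 7 planned results were planned before the values were seen. Tests of GC content and gene length, of the control siRNA and of a weaker response were planned ahead. The results to which these were applied were known only after the values had been seen. All other tests here were chosen after the result was seen.

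The 9 libraries fall into 3 expression sets that cross the siRNA groups. The authors' gene tables and sequencing depth are excluded as the cause of the split between sets 1 and 2. These sets share both and still reach at most r = 0.744, against at least 0.927 inside the sets. For set 3, which has its own gene table and depth, this test cannot decide. Mixing of one culture with another in varying shares is excluded, because each set lacks at least 13 genes (at most 0.1 FPKM) that every library of the other sets has at 5 FPKM or more. Cells of different origin under one label remain possible for all 3 sets. The 29 genes absent from set 2 include 7 pairs of chromosomal neighbours (0.163 in random draws, permutation p = 0.0003 after multiplying by the 3 sets). Among them are CDIP1, UBALD1, MGRN1, GLYR1 and UBN1 on chromosome 16. ARMCX6 and ARMCX3, and TCEAL8 and TCEAL9, which lie close together on the X chromosome, were absent too. The test does not tell a lost stretch from neighbours that lost expression otherwise. The same permutation test cannot decide for set 1 (34 absent genes, 0 pairs, permutation p = 1) or for set 3 (13 absent genes, 1 pair, permutation p = 0.0903). It sees only lost stretches of chromosome, and cells of different origin can differ without them. The siNC libraries of sets 1 and 3 correlated at 0.707. Between these 2 controls, CDH2 was at 0 and 17.7 FPKM, THY1 at 0.0173 and 43.6, and COL1A2 at 0.00613 and 56.2. GSTP1 was at or below 0.0179 FPKM in set 1 and at 89.4 or more in every other library. No biological explanation was tested.

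More genes than random order would give lie on the same side of their own control in all 6 knockdown libraries (2439). Only 1 of the 24 choices of control, the siNC libraries themselves, gave as many, and the highest other gave 2102. That other choice gave 25 genes in the pooled fit, against 1 for the siNC libraries. A share of 1 in 24 is the smallest this test can give, and the count was chosen after the values had been seen. Random grouping is therefore not excluded. GC content or gene length bias is excluded, because removing both trends left 2477 genes, with 2262 for the highest other choice and 1020 on average. An effect of the control siRNA itself is open, since 0 of the 9 libraries were without siRNA. Without a shared control, the set fit had a correlation of 0.254 between the fold changes of the 2 siRNAs. Whether the shared changes follow a loss of WFDC21P cannot be told, since siWFDC21P-1 replicate 3 had no detectable fall of it.

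The library siWFDC21P-2 replicate 1 lies next to siNC replicate 3. A weaker response to the same siRNA remains possible. The difference of this library from the control correlated at 0.210 with the siWFDC21P-1 fold change, against 0.256 and 0.194 for replicates 2 and 3. This correlation does not measure how strong a response is, so it cannot decide. The names of the siWFDC21P-2 libraries also end in different numbers, and whether these mark different siRNAs is not stated. Less knockdown of WFDC21P is open (1.53 times replicates 2 and 3 together, counting interval 1.12 to 2.07, with no measure of the spread between libraries). A shared culture or preparation day of the pair is open too, with r of at most 0.942 between this pair and that of replicates 2 and 3 and of at least 0.985 inside the pairs.

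In 5 lists every siWFDC21P-1 library moved one way and every siWFDC21P-2 library the other, and these differences were not tested. They cannot be told apart from differences between the sets, and knockdown libraries of one set share a control. Some medians lay near 0. With siWFDC21P-1 they were -0.03 to -0.009 for the epithelial to mesenchymal transition and reached -0.0009 for fatty acid synthesis. With siWFDC21P-2 they were 0.04 to 0.15 for matrix proteases and inhibitors. As the mean over libraries of the list median, siWFDC21P-2 minus siWFDC21P-1, the difference was 0.47 for the epithelial to mesenchymal transition, 0.36 for fatty acid synthesis, 0.21 for matrix proteases and inhibitors, 0.64 for TGF-beta and SMAD3 targets and -1.59 for the unfolded protein and integrated stress response. The same held for RNU6-611P (1.98), MIR6753 (2.23) and SNORA75 (-1.78), as log2 fold changes with the sets in the model. Among genes listed with style B alone, 31 of 104 with a mean of at least 1 FPKM were higher in all 3 siWFDC21P-2 libraries than in siNC replicate 3 and 22 were lower, where chance gives 26 each way. Among those listed with style A alone, 46 of 329 were higher and 55 lower (chance 54.8). Groups of 3 libraries were not tested for outliers.

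Other splits of the libraries were run for each count. The real split is counted among them. For siWFDC21P-1, 10 of 10 splits gave at least the 0 genes observed, and the highest, 4575, is the split that separates set 1 from the rest; for the lists, 8 of 10 gave at least 6 (highest 13). For siWFDC21P-2, 10 of 10 gave at least 0 genes (highest 0), and 2 of 10 gave at least 14 lists (highest 17), and for the difference between the siRNAs 10 of 10 gave at least 0 genes (highest 0). Splits into 10 cannot reach a share under 0.05. Of 100 drawn splits, 100 gave at least the 0 genes shared by both siRNAs (highest 3259), and 3 gave at least the 863 genes of the naming style (highest 2227), 1 of them being an equivalent model. With the sets in the model, 1 of 6 choices of control gave at least 3 genes for siWFDC21P-1 (highest other 0) and 4 of 4 at least 0 for siWFDC21P-2, too few choices for a verdict. For the pooled fit, 2 of 24 choices gave at least 1 gene (highest other 25) and 13 of 24 at least 10 lists (highest other 14), so neither pooled count stands apart from random grouping.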

How the results depend on the processing

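The set term, limma-voom and the fits without the libraries of set 2 were chosen after seeing the data. Of the recomputed comparison values 264 stayed the same, 56 moved and 3 reversed, and of those of named genes 2335 stayed, 25 became stronger, 10 weaker and 22 reversed. No list passing with the naming style passed in the other direction under another setting. Lists that changed sign without passing were not counted. The count of genes for both siRNAs was 0 wherever 1 choice was changed. It was 41 with 2 changed together (the set term, without siWFDC21P-2 replicate 1). Unless stated otherwise, the cause was not tested.

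Without the naming-style term, which lets set 3 be compared with controls of other sets, and equally with the replicate block without that term, WFDC21P reversed to 0.31 for siWFDC21P-2. N4BP3 (0.10) and KRT8 (0.66) reversed for siWFDC21P-1, and HMOX1 (1.35), EGR1 (1.39), IFI6 (0.45), PSAT1 (0.15), IL6 (0.10), IFI44L (0.21), UGCG (0.33), CXCL8 (2.53) and GLRX5P2 (0.26) for siWFDC21P-2. In both settings 14 lists passed for siWFDC21P-1 and 7 for siWFDC21P-2. The replicate block with the naming style gave 3 lists for siWFDC21P-1 and 55 genes for the naming style. Replicate numbers do not pair the libraries: 2 of 9 same-number pairs had a correlation over 0.1.

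For siWFDC21P-1, the genes became 3 with the set term and 2 without set 2 (SNORD65C and AP001781.1), and the lists became 2 with a pseudocount of 0.1, 3 with no filter, 2 at a mean of at least 5 FPKM and 12 with the set term. With no filter, 14 genes passed for siWFDC21P-2 and 9 for the difference between the siRNAs. The naming style gave 489 genes at a mean of at least 5 FPKM, where fewer genes are tested, 505 with limma-voom and 2984 without set 2.

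With the sets in the model, the 3 genes of siWFDC21P-1 became 0 with no filter, 26 at a mean of at least 5 FPKM, 0 with median-of-ratios scaling, 16 with quantile normalization and 14 with limma-voom, and the 0 of siWFDC21P-2 became 17 with no filter. The pooled count of 1 became 2 with a pseudocount of 0.1 (GANAB and SNORD65C), and 0 with no filter, with median-of-ratios scaling and without set 2. The 2439 genes on the same side became 1567 at a mean of at least 5 FPKM.

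Leaving out 1 library in turn gave, for WFDC21P, -1.63 to 0.23 with siWFDC21P-1, -1.10 to -0.74 with siWFDC21P-2 and -1.24 to -0.52 pooled. Genes ranged from 0 to 3 for siWFDC21P-2, 0 to 1 for the difference and 343 to 1071 for the naming style, and lists from 3 to 10 for siWFDC21P-1 and 13 to 16 for siWFDC21P-2. With the sets, genes ranged from 0 to 153 for siWFDC21P-1, 0 to 902 for siWFDC21P-2 and 0 to 204 pooled. The highest was always without siWFDC21P-2 replicate 1. Pooled lists ranged from 10 to 12. Genes on the same side ranged from 2614 to 3491 with 1 knockdown library left out. Fewer libraries then had to agree, so this count could not fall below the full count. The share that random order would give rises as well. A lone library left in an arm is assumed to vary like the others. Without siNC replicate 3 there is no value for siWFDC21P-2, the naming style, both siRNAs or their difference, WFDC21P has none at a mean of at least 5 FPKM, and robust variances give no camera value. Depth limits WFDC21P where few reads were counted, as in siWFDC21P-1 replicate 1 (2 reads) and in set 2 (4 and 7).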

Other observations

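The tests behind the values in this part were chosen after the result was seen.

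Among the endothelial and leukocyte markers, single genes were abundant in set 2. KDR, an endothelial growth factor receptor gene, was at 19.4 FPKM in the library labelled siNC replicate 2 and at 25.7 in siWFDC21P-1 replicate 3, and at or below 0.01 in the other 7 libraries. Of the other endothelial markers, CDH5 and VWF stayed at or below 0.237 and 0.0719 FPKM in all 9 libraries, PECAM1 was highest in siNC replicate 1 (1.43), ERG in set 1 (1.15 to 4.58) and TEK in siWFDC21P-2 replicate 3 (4.94). EGFL7 was at 1.97 to 12.01 FPKM, highest in set 1, and ESAM was at 1.99 and 1.93 in set 2 and at or below 0.651 elsewhere. CD14, a monocyte marker, was at 36.1 and 29.6 FPKM in the 2 libraries of set 2 and at 0.32 to 8.70 elsewhere, while the leukocyte gene PTPRC stayed at or below 0.16 in all 9. Of the basal epithelial markers, KRT5 (12.1 and 15.7 FPKM), KRT14 (8.63 and 19.3) and DSC3 (18.4 and 24.8) were abundant in set 2 and near 0 in set 1, SFN was abundant in both (75.5 and 91.1 in set 2, 70.1 to 97.8 in set 1), and KRT6A and DSG3 stayed at or below 0.0129 FPKM in set 2. Genes absent from set 1 and present elsewhere included GSTP1, a glutathione S-transferase, and NOTCH3, those absent from set 2 included AXL and ZEB1, and those absent from set 3 included MAL2 and RBM47.

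Without siWFDC21P-2 replicate 1 and with the sets in the model, 153 genes passed for siWFDC21P-1, 902 for siWFDC21P-2 and 41 for both with the same sign. Of these 34 were higher and 7 were lower, the latter being KLHDC7B, IER3, BAK1, CDKN1A, MCL1, PHLDA1 and PLEKHF1. This library was left out after its closeness to the control had been seen. How many genes both would share by chance was not tested, since the 2 contrasts take their spread from 1 fit. In that fit the spread within set 3 rests on siWFDC21P-2 replicates 2 and 3 alone, which correlated at 0.986. No library of the siWFDC21P-1 contrast was left out. GANAB kept its fold change of 1.74 there, and its SE fell from 0.16 to 0.13. The added calls for siWFDC21P-1 thus rest on a smaller estimate of the spread.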
